A study of Mus musculus with 10 samples.

How the data were processed

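RNA was sequenced from 10 samples of C57BL/6 mouse stomach. Per the labels, 4 samples were ulcerated gastric tissue, 4 were uninjured gastric tissue of healthy controls, 1 was intact stomach tissue and 1 was gastric organoids, which are epithelial structures grown in culture. The labels give an age of 2 to 3 months. Groups and the replicate numbers of the ulcerated and uninjured samples were taken from the titles, which give no number for the intact tissue and organoid samples, and the series design sets ulcerated against uninjured tissue and organoids against intact tissue.

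The authors deposited 1 table of whole-number read counts per gene, with no normalization, keyed by NCBI gene number. Per the submitters' processing notes, bcl2fastq, CASAVA 1.8, TopHat, DESeq and the mouse genome build mm10 were used, with no role or order stated. The counting tool, the gene annotation and the handling of strand and of reads that match several genes are not given in the sources used here. The table held 24415 genes. All its lines named a gene, so none was left out of the library sizes for that reason. In the 8 ulcerated and uninjured columns 4 genes were blank, while the other 2 columns held values for them, so these 4 genes entered the organoid comparison only. Symbols and coordinates came from a RefSeq gene table of the assembly GRCm38.p6, which is the build named mm10, and 24334 of the 24415 gene numbers matched it. The 81 others were tested and counted but are not named. Of the genes with at least 100 counts in all, 86 had counts identical to those of another gene in every library, such as the hemoglobin genes Hba-a1 and Hba-a2. Reads of such copies cannot be told apart, and their values are uncertain.

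The main test of ulcerated against uninjured tissue was edgeR 4.0.16 in R 4.3.3 on the deposited counts of these 8 libraries. It used TMM scaling, the edgeR expression filter by group with its default settings and the quasi-likelihood F-test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was derived from the F statistic. CPM values are counts scaled to a common library size with TMM factors. The score of a gene list in a library is the mean of log2(CPM + 0.5) over its tested members. Scores were compared with a two-sided exact permutation test over the 35 splits of 8 libraries into 4 and 4, which cannot give a p below 0.0286.

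Before the data were examined, 30 gene lists with 386 members in all were fixed from general knowledge of stomach cell types, immune and stromal cells, neighbouring tissues and injury processes, and 385 of the members were in the table. They covered SPEM markers, parietal, chief, surface mucous and enteroendocrine cells, gastric stem and progenitor cells, general epithelium, proliferation, neutrophils, macrophages and monocytes, T cells, B and plasma cells, cytokines and chemokines, interferon response, extracellular matrix, matrix proteases and inhibitors, endothelium and angiogenesis, smooth muscle, enteric neurons and glia, adipocytes, erythroid cells, pancreatic acinar cells, hepatocytes, forestomach squamous epithelium, intestinal epithelium, Hedgehog signalling, growth factors and receptors, hypoxia and glycolysis, mitochondrial respiration, and immediate early and heat shock genes. The 28 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The rotation test fry asked instead whether the genes of a list moved, on balance, in 1 direction, without a comparison with other genes.

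Genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 2 and no overlap of the groups. It added all members of the SPEM, parietal and chief cell lists, and from each other list up to 4 members past the threshold, those with the highest expression first, or up to 2 members where none passed. Predicted, ribosomal protein and mitochondrially encoded genes were skipped among the largest changes. For organoids, the rule took the 10 largest and the 10 smallest ratios and up to 4 members of each list with the highest mean CPM, and all members of the SPEM, parietal and chief cell lists. Not every gene that the rule took is named. Genes outside this rule are named as such where they appear.

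Organoid and intact tissue had 1 library each, so no test was run. The ratio of TMM-scaled CPM was taken with each library floored at 3 counts, and genes with at least 100 counts in 1 of the libraries were sorted by whether they differed by at least 4-fold. For genes with 1 or 2 counts in a library the text gives the ratio without the floor, with its counting interval. For genes with 0 counts it gives the ratio with the floor, which is not a lower limit. Counts and list medians use the floor. Within the gene lists the minimum of 100 counts was not applied, and only members at or below the floor in both libraries were left out. Intervals are exact 95% Poisson intervals for a CPM and exact binomial ones for a ratio. They cover counting error only, and reads are not independent molecules. The floor was 0.160 CPM in intact tissue and 0.186 CPM in organoids. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on expression in 25 bins.

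The total count per library was 11850556 to 25360413. Replicates of a group differed far more than sampling noise, with a chi-square per degree of freedom of 69.1 to 708 for pairs of libraries over genes with at least 50 counts, so no library was counted as a duplicate. The biological coefficient of variation was 38.8%. On simulated counts of 15720 genes with 200 of them changed, the edgeR test recovered 38.2% of 2-fold, 87.9% of 4-fold and 92.4% of 16-fold changes, and 2.03% of its calls were false. The changed genes were drawn from those with higher expression only, so the shares recovered do not hold for genes of low expression. On the same data 27.4% of the calls of DESeq2 1.42.0 were false, against 2.68% for limma-voom. With the chief cell list lowered 4-fold in a simulation, that list was called and 0 of the 27 others were. The simulated genes varied independently, while the estimated inter-gene correlation in the data reached 0.88 for parietal cells and 0.96 for hepatocytes. The simulation therefore shows neither the false share of the gene tests nor how often camera calls a list falsely in these libraries.

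Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, total counts only, no filter, a filter of 10 CPM in 4 libraries, DESeq2 and limma-voom as tests, the replicate number as a block, all 10 libraries in 1 fit, leaving out each library in turn, and for organoids total counts, DESeq2 size factors, a count minimum of 30 and a floor of 10 counts. The alternatives added after the data were seen were the hepatocyte list score as a covariate, only the 5 libraries with the higher hepatocyte scores, and leaving out both ulcerated replicates 1 and 2.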

Results

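Read counts per gene were analysed from 10 libraries of mouse stomach RNA. Ulcerated and uninjured gastric tissue had 4 libraries each, and intact stomach tissue and the gastric organoids grown from it had 1 each. The total count was 25360413, 19132024, 16593815 and 12542631 in ulcerated replicates 1 to 4, 17904026, 19277363, 19723116 and 11850556 in uninjured replicates 1 to 4, 20830327 in intact tissue and 14495643 in organoids. The labels number the samples but do not say that they came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

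The first comparison set ulcerated against uninjured tissue, in a study concerned with ulcer repair and with spasmolytic polypeptide-expressing metaplasia (SPEM), a mucous cell lineage that appears in injured gastric glands. In ulcerated tissue, genes of neutrophils, macrophages and matrix remodelling rose, and genes of acid-secreting parietal cells, enzyme-secreting chief cells, endocrine cells and enteric neurons fell, by single genes past the test and by camera with a preset correlation. With an estimated correlation 0 of 28 gene lists passed, and the adjusted p was 0.243 for parietal, 0.193 for chief and 0.289 for enteroendocrine cells. Saa3, an acute phase protein (gene 20210, chromosome 7, 46711998 to 46719615, build mm10), rose to 115 ± 47.6 CPM in ulcerated from 1.35 ± 0.819 CPM in uninjured tissue (SD, n = 4 each), a log2 fold change of 6.38 with an SE of 0.57 and an adjusted p of 0.0161 by edgeR's quasi-likelihood test. Cblif, which encodes gastric intrinsic factor (gene 14603, chromosome 19, 11747543 to 11763447), fell to 408 ± 309 from 2788 ± 565 CPM (SD, n = 4 each), a log2 fold change of -2.77 with an SE of 0.54 and an adjusted p of 0.0247 by the same test. In all, 865 of 15720 tested genes were higher and 950 lower in ulcerated tissue at a Benjamini-Hochberg adjusted p under 0.05, and 602 and 406 of these differed at least 2-fold. The groups did not overlap in 18.9% of the tested genes, against 2.86% expected for a single gene under random grouping. Genes varied together in these libraries, so the share under a random grouping may lie far from 2.86%, and its spread was not measured.

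Among the other large rises, by log2 fold change, were Sds (5.64), Cxcl5 (5.12), S100a8 (4.21), Timp1 (4.04), Mmp9 (3.93), Mmp10 (3.84), Adam12 (3.74) and H19 (3.65). Cxcl5 is a neutrophil chemokine, S100a8 a calcium-binding protein of neutrophils and Timp1 an inhibitor of metalloproteinases. Sds, a liver enzyme of serine breakdown, had 40.4, 39.5, 1.32 and 15.2 CPM in ulcerated replicates 1 to 4. The 10 largest falls were Clps (-3.55), Gdf9 (-3.35), Egf (-3.16), Gper1 (-3.15), Pappa2 (-3.06), Glp1r (-2.95), Pdia2 (-2.91), Cblif (-2.77), Bhlha15 (-2.76) and Tmed6 (-2.76). Egf, the epidermal growth factor, fell to 3.02 ± 1.88 from 26.7 ± 13.8 CPM (SD, n = 4 each). Clps, a colipase, fell to 1504 ± 1568 from 17673 ± 7407 CPM (SD, n = 4 each).

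The libraries were uneven. The first principal component held 70.4% of the variance and placed ulcerated replicate 3 at 26.5 and uninjured replicate 1 at -10.5, between the other ulcerated libraries (-115 to -56.6) and the other uninjured ones (71.8 to 98.6). Hepatocyte transcripts put the libraries in nearly the same order. The hepatocyte list score was 11.2, 11.5, 6.50 and 9.30 in ulcerated replicates 1 to 4 and 8.45, 3.86, 2.88 and 3.29 in uninjured replicates 1 to 4. By edgeR, 0 genes passed without ulcerated replicate 1, ulcerated replicate 2 or uninjured replicate 3, where 3914, 3976 and 3873 genes had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 1158, 1254 and 1383 genes higher and 1063, 1109 and 1095 lower. The counts higher and lower were 8 and 2 without uninjured replicate 4, 406 and 544 without ulcerated replicate 4, 594 and 324 without uninjured replicate 1, 2406 and 1911 without ulcerated replicate 3, 541 and 761 with total counts as the only scaling, which moved the median of all genes by -0.11 on the log2 scale, and 2 and 3 with the hepatocyte score as a covariate, which was added after the data were seen. Of the 1815 genes called, 1814 kept their direction in all 8 fits that left out 1 library, and 1810 were also called in that direction by DESeq2. These genes were chosen by their difference in the same 8 libraries, so neither count is an independent check.

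Markers of SPEM were mostly higher in ulcerated tissue, but only Cd44, a cell surface receptor, passed the test over all genes. It rose to 98.0 ± 8.67 from 29.4 ± 8.15 CPM (SD, n = 4 each), a log2 fold change of 1.74 with an SE of 0.20 and an adjusted p of 0.0166 by edgeR. Of the 16 tested markers 1 rose, 0 fell and 15 did neither, and adjusted over the list alone 9 rose and 1 fell. Counts adjusted over a list alone, here and below, hold no comparison with other genes. Of all 15720 tested genes 5176 had an unadjusted p under 0.05 by edgeR. Tff2, the spasmolytic polypeptide itself, had 2006 ± 591 against 1315 ± 610 CPM (SD, n = 4 each) and an adjusted p of 0.285. The log2 fold changes of the others that did not pass were 3.09 for Wfdc18, 2.70 for Cftr, 2.19 for Dmbt1, 2.09 for Muc4, 1.32 for Wfdc2, 1.14 for Aqp5, 0.99 for Gkn3, 0.89 for Glipr1, 0.83 for Gpx2, 0.82 for Clu, -0.11 for Mal2, -0.41 for Sox9, -0.86 for Muc6 and -1.07 for Olfm4. The list had a median of 0.94 and was higher by camera with an adjusted p of 0.000872, which became adjusted p = 0.313 with an estimated correlation. Its score was 6.88 ± 0.312 in ulcerated and 5.84 ± 0.432 in uninjured libraries (SD, n = 4 each), without overlap.

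Genes of parietal cells, which secrete acid, fell together. Of 13 tested members 8 fell, 0 rose and 5 did neither, and adjusted over the list alone all 13 fell. Slc4a2, an anion exchanger, fell to 174 ± 82.9 from 601 ± 135 CPM (SD, n = 4 each), and log2 fold changes were -1.79 for Slc4a2, -1.83 for the chloride transporter Slc26a9, -1.69 and -1.74 for the potassium channels Kcnq1 and Kcnj15, -2.32 for Slc26a7, -2.32 for the histamine receptor Hrh2, -2.53 for the water channel Aqp4 and -2.43 for the nuclear receptor Esrrb. The proton pump subunits Atp4a and Atp4b had 1271 ± 1091 against 7670 ± 2529 and 568 ± 493 against 3295 ± 996 CPM (SD, n = 4 each), with adjusted p-values of 0.0641 and 0.0636 by edgeR. Clic6 (-2.35), Esrrg (-2.43) and Kcne2 (-2.42) did not pass either. The list median was -2.35, with a camera adjusted p of 1.62e-11 and adjusted p = 0.243 with an estimated correlation. The scores were 4.29, 4.13, 6.00 and 6.13 in ulcerated replicates 1 to 4, lowest in the 2 libraries with the highest hepatocyte scores, and 7.85, 6.89, 7.69 and 7.82 in uninjured ones.

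Genes of chief cells, which secrete digestive enzymes, were also lower. Of 9 tested members 4 fell, 0 rose and 5 did neither, and 7 fell adjusted over the list alone. The members that fell were Cblif, the chaperone Pdia2 (-2.91), and the secretory cell transcription factors Bhlha15 (-2.76) and Xbp1 (-0.47). Pgc, which encodes a pepsinogen, had 8426 ± 8648 against 92284 ± 40831 CPM and the chitinase Chia1 had 652 ± 712 against 14017 ± 9063 CPM (SD, n = 4 each), with adjusted p-values of 0.0696 and 0.0515 by edgeR. Pga5 (-1.96), Rab3d (-0.44) and Rab26 (-0.36) did not pass. The list median was -2.76, with a camera adjusted p of 6.51e-07 and adjusted p = 0.193 with an estimated correlation. The scores were 5.94, 5.42, 6.87 and 7.29 in ulcerated replicates 1 to 4, lowest in the same 2 libraries, and 8.57, 8.52, 9.19 and 9.03 in uninjured ones. With the hepatocyte score as a covariate the medians were -2.13 for chief cells, -1.87 for parietal cells and 1.53 for SPEM markers, and without ulcerated replicates 1 and 2 they were -2.15, -1.62 and 1.21.

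**Figure D1:**
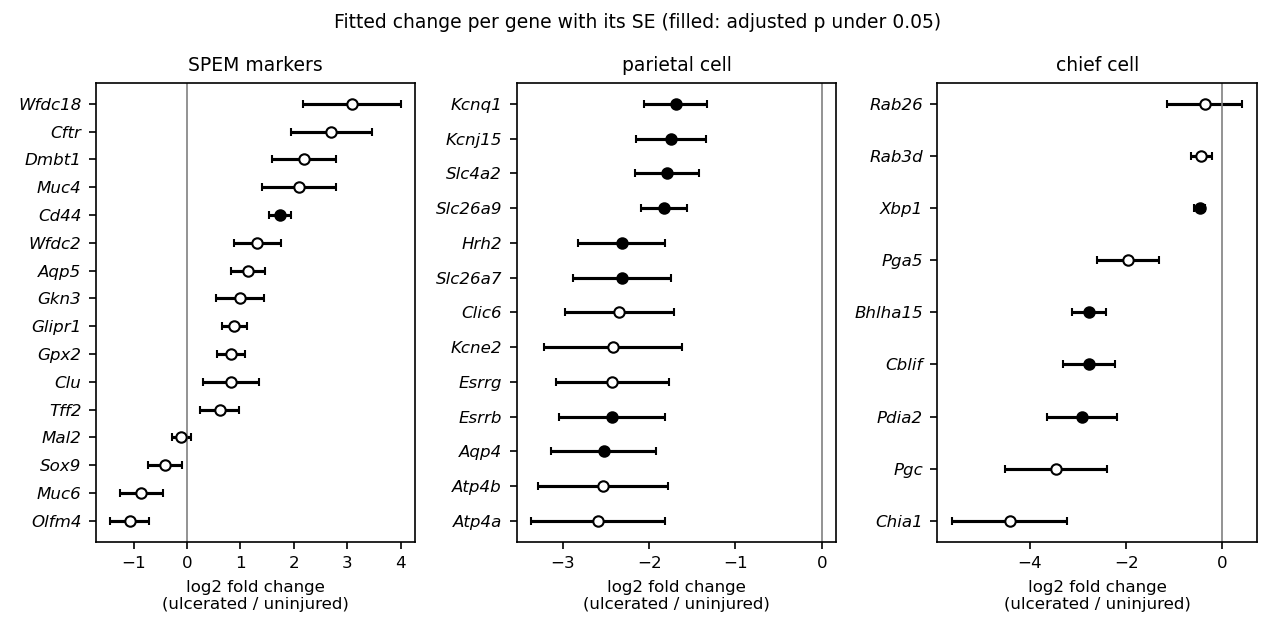
Fitted log2 fold change of each tested SPEM, parietal and chief cell marker in ulcerated against uninjured tissue (n = 4 each), with bars of 1 SE and filled points for an adjusted p under 0.05. Of 16 SPEM markers only Cd44 is filled, while 8 of 13 parietal and 4 of 9 chief cell markers are filled and lie below 0.

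Of the other epithelial lists, surface mucous cells had 0 of 11 members past the edgeR threshold and 0 adjusted over the list alone. Their secreted proteins Gkn1 and Gkn2 had 14905 ± 5429 against 21271 ± 2695 and 13332 ± 4467 against 18186 ± 960 CPM (SD, n = 4 each). The list median was -0.51, with a camera adjusted p of 0.00841 and adjusted p = 0.483 with an estimated correlation. This list lost its call in 5 of 21 alternatives, that one included, with medians from -0.80 to -0.003. Of 12 enteroendocrine genes 6 fell and 6 did not pass, and 6 fell adjusted over the list alone. Among them, chromogranin A (Chga) fell to 80.1 ± 52.7 from 427 ± 127, ghrelin (Ghrl) to 197 ± 106 from 728 ± 151 and somatostatin (Sst) to 43.7 ± 30.4 from 222 ± 33.1 CPM (SD, n = 4 each), and Isl1 had a log2 fold change of -1.27. The list median was -1.04, with a camera adjusted p of 0.000152 and adjusted p = 0.289 with an estimated correlation. Of 12 gastric stem and progenitor genes 4 fell and 8 did not pass, and adjusted over the list alone 5 fell and 1 rose. The log2 fold changes were -0.73 for Lrig1, -0.78 for Znrf3, -0.55 for Lgr5 and -1.32 for Tnfrsf19, and the list median of -0.24 had a camera adjusted p of 0.00433 and adjusted p = 0.243 with an estimated correlation. General epithelium had 0 of 12 members past the threshold, 0 adjusted over the list alone, with keratin Krt8 at 2310 ± 891 against 2140 ± 558 and Krt19 at 1668 ± 617 against 1600 ± 441 CPM (SD, n = 4 each). Its median was -0.01 while its mean was 0.27 and the camera test pointed upward, with an adjusted p of 0.687. Of 17 proliferation genes Cdk1 (0.68), Aurkb (0.59) and Bub1 (0.82) rose and 14 did not pass, and 8 rose adjusted over the list alone. The proliferation median was 0.48, with a camera adjusted p of 0.0012 and adjusted p = 0.483 with an estimated correlation.

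Genes of myeloid cells rose in ulcerated tissue. Of 9 neutrophil genes 5 rose and 4 did not pass, and 8 rose adjusted over the list alone. S100a8 rose to 29.2 ± 12 from 1.52 ± 2.30, the gelatinase Mmp9 to 52.9 ± 16.9 from 3.41 ± 3.54 and the growth factor receptor Csf3r to 32.0 ± 7.49 from 5.67 ± 3.35 CPM (SD, n = 4 each), and Il1r2 had a log2 fold change of 2.04. Of 16 macrophage and monocyte genes 12 rose and 4 did not pass, and 14 rose adjusted over the list alone. Lysozyme (Lyz2) rose to 322 ± 67.7 from 73.8 ± 31.4 CPM (SD, n = 4 each), and the log2 fold changes were 1.8 for the receptor Csf1r and 1.67 and 1.66 for the complement genes C1qa and C1qb. Of 18 cytokines and chemokines 5 rose and 13 did not pass, and 8 rose adjusted over the list alone. Cxcl5 rose to 19.9 ± 6.04 from 0.539 ± 0.633 CPM (SD, n = 4 each), and the log2 fold changes were 3.48 for Ccl7, 2.54 for Ccl2 and 3.25 for the nitric oxide synthase Nos2. The list medians were 3.34 for neutrophils, 1.75 for macrophages and 2.51 for cytokines, with camera adjusted p-values of 5.23e-08, 4.19e-12 and 1.76e-09. These became adjusted p = 0.193, 0.243 and 0.243 with an estimated correlation. In the same libraries the macrophage score was 5.67, 5.58, 4.45 and 5.17 in ulcerated replicates 1 to 4, highest in the 2 with the highest hepatocyte scores.

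Genes of lymphoid cells had low expression. Of 6 T cell genes Cd3g (2.44) and Icos (2.13) rose and 4 did not pass, 4 rose adjusted over the list alone, and the median of 1.69 had a camera adjusted p of 0.00307 and adjusted p = 0.313 with an estimated correlation. Of 4 B and plasma cell genes 0 passed by edgeR, 2 rose adjusted over the list alone, the median was 1.69 and no list test was run. Jchain and Cd79b had 3.81 ± 1.75 against 2.24 ± 0.972 and 1.98 ± 1.09 against 0.700 ± 0.415 CPM (SD, n = 4 each). Of 15 interferon response genes Ifit2 (0.94) and the chemokine Cxcl10 (1.94) rose and 13 did not pass, with 2 adjusted over the list alone. The interferon median was -0.02 while the mean was 0.22 and the camera test pointed upward, with an adjusted p of 0.252.

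Genes of matrix and its remodelling rose. Of 13 matrix proteases and inhibitors 11 rose and 2 did not pass, and all 13 rose adjusted over the list alone. Timp1 rose to 38.9 ± 17.5 from 2.32 ± 1.28, the disintegrin Adam12 to 42.1 ± 22.8 from 3.12 ± 1.16, the membrane metalloproteinase Mmp14 to 187 ± 84.0 from 36.1 ± 17.6 and the urokinase receptor Plaur to 34.6 ± 10.6 from 11.1 ± 6.65 CPM (SD, n = 4 each). Of 19 extracellular matrix genes 6 rose and 13 did not pass, and 17 rose adjusted over the list alone. The collagens Col1a1 and Col1a2 rose to 2275 ± 1181 from 432 ± 273 and to 1831 ± 1018 from 398 ± 177 CPM (SD, n = 4 each), and log2 fold changes were 1.74 for Sparc and 2.63 for Thbs1. The list medians were 2.37 for proteases and 1.72 for matrix, with camera adjusted p-values of 1.62e-11 and 3.92e-08, and adjusted p = 0.193 and 0.313 with an estimated correlation. Ulcerated replicate 3, the ulcerated library with the lowest hepatocyte score, had a matrix score of 6.55, within the uninjured range of 5.90 to 7.02, while the other ulcerated libraries had 8.05, 8.23 and 8.47.

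Of 14 endothelial and angiogenesis genes Cdh5 (1.42), Tie1 (0.87) and the peptide Apln (2.25) rose and 11 did not pass, and adjusted over the list alone 7 rose and 1 fell. The median was 0.47, with a camera adjusted p of 0.00543 and adjusted p = 0.483 with an estimated correlation. The list lost its call in 5 of 21 alternatives, that one included, with medians from 0.02 to 0.60, and its scores overlapped between the groups. Of 11 smooth muscle genes 3 fell and 8 did not pass, and 7 fell adjusted over the list alone. Smooth muscle myosin (Myh11) fell to 444 ± 77.8 from 917 ± 205 CPM (SD, n = 4 each), with Synm at -0.97 and Lmod1 at -0.86 on the log2 scale. Of 10 enteric neuron and glia genes 7 fell and 3 did not pass, and all 10 fell adjusted over the list alone. The log2 fold changes were -1.29 for the receptor Ret, -1.59 for the neuronal synthase Nos1 and -0.98 for Uchl1. The medians were -0.65 for smooth muscle and -1.20 for enteric neurons and glia, with camera adjusted p-values of 4.88e-05 and 2.66e-07, and adjusted p = 0.289 and 0.193 with an estimated correlation. Of 16 genes of mitochondrial respiration 6 fell and 10 did not pass, and all 16 fell adjusted over the list alone, among them Cox4i1 (-0.68), Uqcrc1 (-0.62), Uqcrfs1 (-0.82) and Sdhb (-0.61). The median was -0.61, with a camera adjusted p of 2.45e-07 and adjusted p = 0.313 with an estimated correlation.

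Markers of neighbouring tissues were uneven between libraries, with high hepatocyte scores in 5 libraries, high squamous scores in 4 and a high acinar score in 1. Of 12 hepatocyte genes 0 passed by edgeR and 0 adjusted over the list alone, and the median was 4.08, with a camera adjusted p of 3.67e-05 and adjusted p = 0.393 with an estimated correlation. Albumin (Alb) reached 12206, 15918, 291 and 2454 CPM in ulcerated replicates 1 to 4 and 1915, 29.0, 9.06 and 8.09 CPM in uninjured ones, and hemopexin (Hpx) had a log2 fold change of 4.40 with an SE of 2.04. Of 12 genes of forestomach squamous epithelium 0 passed and 0 adjusted over the list alone, with scores of 7.17, 5.39, 1.41 and 5.6 in ulcerated and 6.23, 1.53, 1.55 and 0.513 in uninjured replicates 1 to 4. The squamous median was 1.25, with a camera adjusted p of 0.018 and adjusted p = 0.581 with an estimated correlation, and the keratins Krt1 and Krt13 reached 1324 and 648 CPM in ulcerated replicate 1. Of 9 pancreatic acinar genes only Clps, which was high in every uninjured library, fell, and adjusted over the list alone 5 rose and 1 fell. The acinar score was 10.5 in ulcerated replicate 1 and 2.45 to 3.94 in the other 7 libraries, and the median of 8.22 had a camera adjusted p of 0.481.

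The remaining lists had 0 to 2 members past the test. By edgeR 0 of 6 intestinal genes (0 adjusted over the list alone) passed, with a median of 0.28 and Lgals4 at 0.87 and Hnf4a at 0.84, 0 of 9 Hedgehog genes (0 adjusted over the list alone), with a median of -0.26 and Shh at -0.37 and Ihh at -0.29, and 0 of 12 hypoxia and glycolysis genes (0 adjusted over the list alone), with a median of -0.08 and Ldha at 0.39 and Eno1 at -0.28. Their camera adjusted p-values were 0.416, 0.252 and 0.536. The same test passed 0 of 4 adipocyte genes (0 adjusted over the list alone), with Fabp4 at -0.70 and Lipe at -0.62 and a median of -0.66, and 0 of 5 erythroid genes (0 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.627. Hba-a1 and Hba-a2 had identical counts and an uncertain log2 fold change of 0.17. Immediate early and heat shock genes had 0 of 12 past the threshold (0 adjusted over the list alone), with Junb at 0.26 and Jun at -0.15, a median of 0.47, a camera adjusted p of 0.0366 and adjusted p = 0.483 with an estimated correlation. Their list lost its call in 6 of 21 alternatives, that one included, with medians from 0.25 to 0.81. Of 16 growth factors and receptors Tgfb1 rose (1.27), Egf fell and 14 did not pass, with 5 rising and 1 falling adjusted over the list alone, a median of 0.40 and a camera adjusted p of 0.102. In all, 12 lists were higher and 8 lower of 28 tested by camera and 0 with an estimated correlation, while fry called 8 higher and 7 lower. Of the other splits of the 8 libraries into 4 and 4, 2 also reached 20 list calls. The scores of 12 lists did not overlap between the groups, each with an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.0714 adjusted over the 30 lists. They were those of SPEM markers, parietal and chief cells, stem and progenitor cells, neutrophils, macrophages, T cells, cytokines, proteases, smooth muscle, enteric neurons and glia, and mitochondrial respiration.

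**Figure D2:**
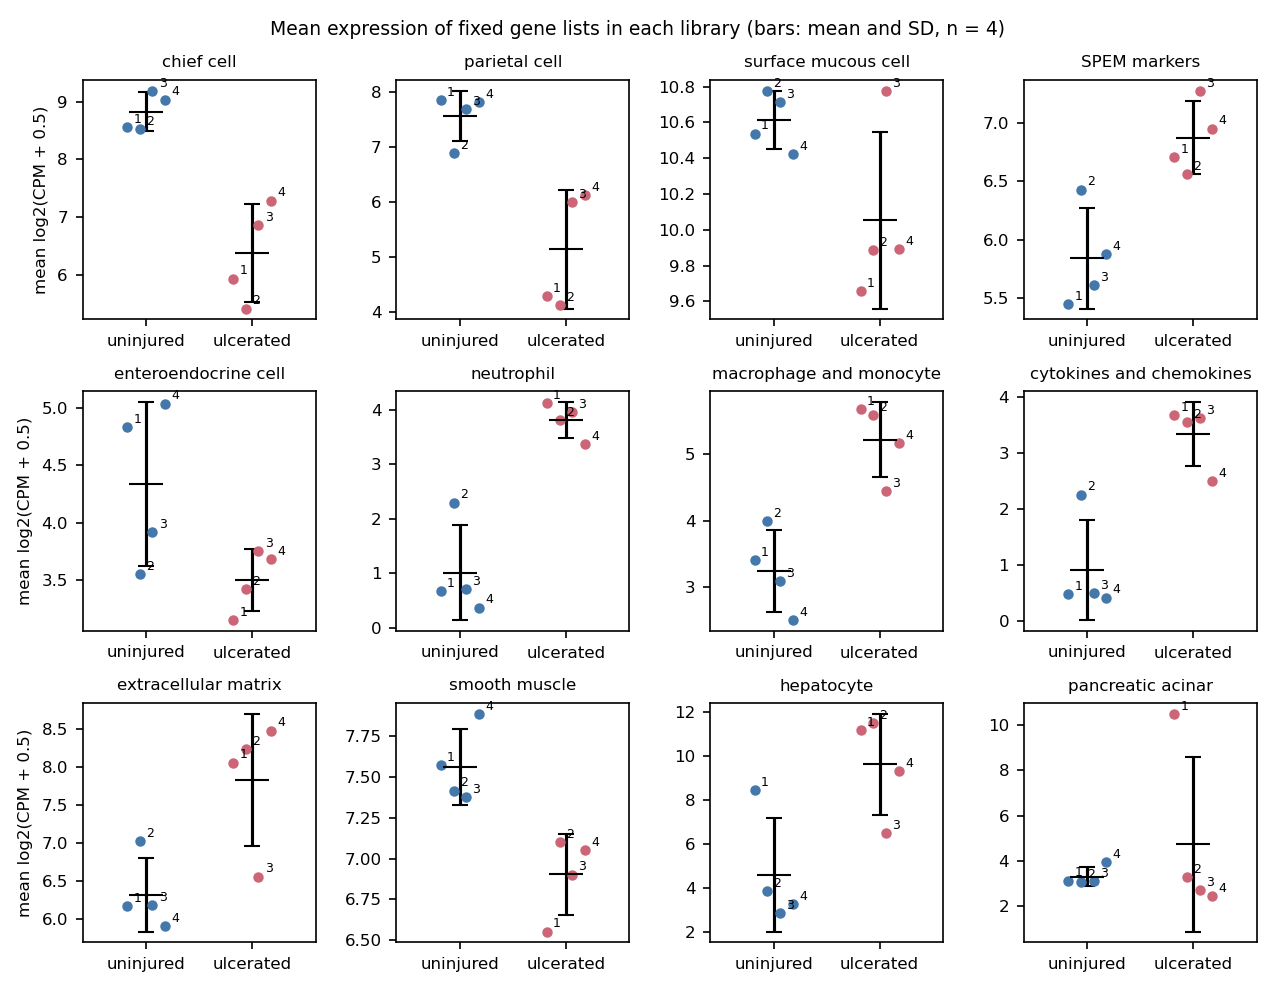
Score of 12 gene lists, the mean of log2(CPM + 0.5) over their genes, in each uninjured (blue) and ulcerated (red) library, numbered by replicate, with bars for the mean and SD (n = 4). Chief and parietal cell scores lie lower and neutrophil, macrophage and cytokine scores higher in all 4 ulcerated libraries, while the hepatocyte score of uninjured replicate 1 (8.45) lies above that of ulcerated replicate 3 (6.50) and the acinar score is high in ulcerated replicate 1 alone (10.5).

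The second comparison set cultured gastric organoids against the intact stomach tissue they were derived from. The organoid library had higher expression of SPEM markers, glycolytic, proliferation, cytokine and interferon response genes, and far lower expression of genes of parietal, chief, surface mucous and endocrine cells and of muscle, vessels and blood. With 1 library each, these differences have no replicate check and describe only these libraries. Aqp5, a water channel found on the SPEM list (gene 11830, chromosome 15, 99591028 to 99594829), had 505 CPM (95% interval 494 to 516) in organoids and 0.908 CPM (0.529 to 1.45) in intact tissue, 557-fold higher. The pepsinogen Pgc had 365 CPM (356 to 375) and 246620 CPM (246390 to 246840), 675-fold lower. Of 11101 genes with at least 100 counts in 1 of the libraries, 620 were at least 4-fold higher and 1029 at least 4-fold lower in organoids. With total counts as the only scaling, which moved the median of all genes from 0.11 to 0.41 on the log2 scale, 883 were higher and 908 lower, so the share higher went from 37.6% to 49.3%.

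Among the largest ratios, besides Aqp5, were those of the tight junction genes Cldn2 (758-fold), Cldn4 (250-fold) and Cldn7 (232-fold), the antimicrobial lectin Reg3g (592-fold), mesothelin (Msln, 392-fold) and the chloride channel Cftr (308-fold). Cldn2, Aqp5, Cftr and Reg3g had 0.267, 0.908, 0.320 and 0.320 CPM in intact tissue. The lowest uninjured libraries of the first comparison, which was scaled separately, had 5.09, 12.1, 1.56 and 1.20 CPM. The size of these ratios therefore depends on an intact library that lay below all uninjured ones. Prss22 had 0 counts in intact tissue and was 396-fold higher with the floor. The smallest were those of Chia1 (2324-fold lower), the phospholipase Pla2g1b (1482-fold), the proton pump subunits Atp4b (810-fold) and Atp4a (691-fold), Smim38 (681-fold) and Pgc. Without the floor, Cckar, Kcne2 and Sparcl1, with 2 counts each in organoids, were 1242-fold (counting interval 344 to 10265), 1080-fold (299 to 8922) and 1073-fold (297 to 8861) lower. Tmprss9 had 0 counts in organoids and was 561-fold lower with the floor.

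Of 16 SPEM markers 12 were at least 4-fold higher and 1 at least 4-fold lower in organoids. The list had a median log2 ratio of 3.24, above all 10000 random lists, whose central 95% ran from -0.42 to 0.86. Clu had 9605 CPM against 685 CPM, Gpx2 946 against 31.4, Gkn3 709 against 12.8, Wfdc2 578 against 5.66 and Cd44 133 against 8.33 CPM. The log2 ratios were 4.03 for Dmbt1, 2.68 for Glipr1, 2.31 for Muc4, 2.22 for Mal2, 1.30 for Tff2, 1.14 for Sox9 and 0.32 for Muc6. Wfdc18 had 0 counts in intact tissue and 13 in organoids and was 5.03-fold higher with the floor. Olfm4, with 1 count in organoids, was 70.6-fold lower without the floor (counting interval 12.3 to 2821). Except for Olfm4 and Wfdc18, all SPEM markers were lower in intact tissue than in every uninjured library of the first comparison, which was scaled separately. Organoid Tff2 (1338 CPM) and Sox9 (71.5 CPM) were close to the uninjured means of 1315 and 64.3 CPM. In organoids Muc6, Muc4 and Olfm4, at 358, 23.8 and 0.062 CPM, lay below uninjured means of 2777, 48.5 and 3.53 CPM. The other markers lay above theirs. The rise of the list thus depends partly on this intact library.

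Of 13 parietal cell genes 11 were at least 4-fold lower, with a median of -5.73 below all random lists. Besides the proton pump, Slc26a9 had a log2 ratio of -4.23, Kcnj15 -4.60, Clic6 -3.63, Slc4a2 -2.75, Esrrg -6.20 and Esrrb -5.73. Slc26a7, with 1 count, was 249.6-fold lower without the floor (counting interval 44.5 to 9893), and Hrh2, with 0, was 99.3-fold lower with the floor. Kcnq1 was at -1.11, while Aqp4 was higher in organoids at 1.44. Of 9 chief cell genes 7 were at least 4-fold lower, with a median of -5.15 below all random lists, among them Cblif (-5.15), Pdia2 (-8.06), Pga5 (-8.58), Bhlha15 (-3.28) and Rab26 (-2.11), while Xbp1 was at -0.06 and Rab3d at -0.46. Lipf had 0 counts in both libraries. Of 11 surface mucous genes 7 were at least 4-fold lower and of 12 enteroendocrine genes 8, with medians of -4.38 and -3.38 below all random lists. Gkn1, Gkn2, Psca and Tff1 had log2 ratios of -7.09, -7.38, -4.38 and -2.19, and Ghrl, Chga, Sst and Hdc -5.68, -6.05, -6.12 and -6.62.

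The lists above all random lists were, besides SPEM markers, proliferation (median 1.87), cytokines and chemokines (2.63), interferon response (2.22), and hypoxia and glycolysis (2.75). Examples were Top2a at 1.83 and Pcna at 1.16, the prostaglandin synthase Ptgs2 at 5.32 and Il33 at 2.44, Oasl2 at 4.70 and Irf7 at 3.98, and Pgk1 at 3.29 and Ldha at 2.87. General epithelium (1.42), with Krt18 at 2.51 and Krt19 at 1.84, was at the 99.5th percentile, immediate early and heat shock genes (0.77), with Ier3 at 3.08, at the 98.3rd, and matrix proteases and inhibitors (0.66), with Adam8 at 5.56 and Plaur at 2.99, at the 97.6th.

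Smooth muscle, endothelial, erythroid and extracellular matrix genes were lower in organoids. The medians were -7.24 for smooth muscle, with Myh11 at -7.44 and Des at -8.05, -5.34 for endothelium, with Plvap at -7.65 and Pecam1 at -6.31, -8.33 for erythroid genes and -4.92 for extracellular matrix, with Col3a1 at -5.17, all below every random list. Within the matrix list Spp1, Thbs1 and Fn1 were higher in organoids, at 2.88, 3.71 and 1.49. Squamous epithelium had a median of -4.53, with Krt1 at -7.60, also below every random list, and mitochondrial respiration one of -0.65, with Atp5b at -0.73, at percentile 0.01. Macrophages and monocytes (-2.71, with Lyz2 at -2.81 and Cd14 at 3.87), pancreatic acinar genes (-4.66, with Clps at -9.10), hepatocyte genes (-2.66, with Apoa1 at -8.69) and Hedgehog genes (-3.15, with Shh at -5.23 and Ihh at 0.83) were at percentiles 0.09, 0.08, 0.69 and 0.21. The medians of enteric neurons and glia (-2.69), neutrophils (-1.46), stem and progenitor genes (-0.35, with Prom1 at 3.80), intestinal epithelium (0.81, with Vil1 at 3.34) and growth factors and receptors (0.54, with Areg at 3.70) lay inside the central 95%. T cell, B and plasma cell and adipocyte lists had too few genes above the floor in either library for a percentile. Their medians were 0.10 over 4 genes, -0.52 for 1 gene and -1.11 over 3 genes.

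**Figure D3:**
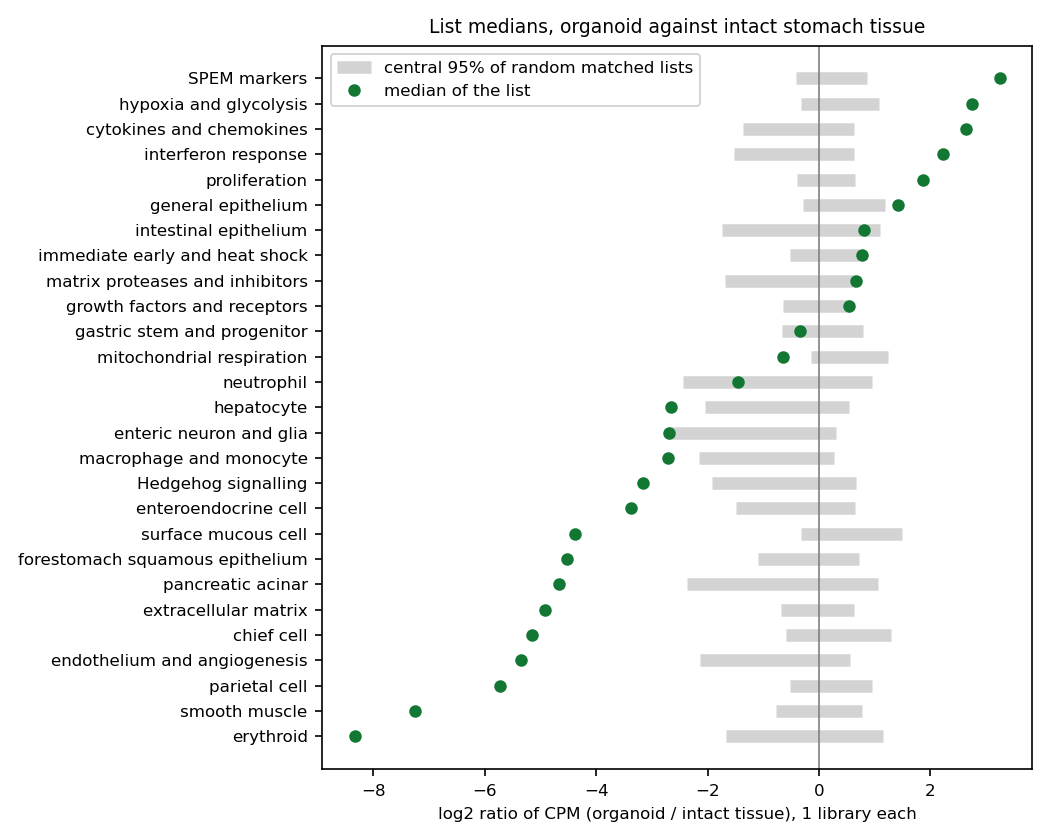
Median log2 ratio of CPM in the organoid against the intact tissue library for each gene list (green points), with grey bars for the central 95% of 10000 random lists of the same size and expression. SPEM markers have the highest median (3.24), and erythroid (-8.33), smooth muscle (-7.24) and parietal cell genes (-5.73) the lowest.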

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

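The tests of dilution, antral tissue, liver tissue, a response to the ulcer and pancreatic tissue and the splits for the gene count were chosen after the results were seen, while the splits for the list count were planned before.

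Chief and parietal cell transcripts were lower in all 4 ulcerated libraries, while liver transcripts were high in these 4 and in uninjured replicate 1, and squamous transcripts were high in all of these 5 libraries except ulcerated replicate 3. Dilution of stomach RNA by such tissue would lower all gastric epithelial genes alike, but relative to the surface mucous score of the same library the chief and parietal score was -4.30 ± 0.81 in ulcerated and -2.42 ± 0.46 in uninjured libraries (SD, n = 4 each). This difference of -1.88 (two-sided exact permutation p of 0.0286, the smallest that 4 against 4 can give) argues against dilution as the whole cause. For more antral tissue, which has few chief and parietal cells, uninjured replicates 1 and 4 were used. Their antral scores (Gast, Pdx1 and Nkx6-3) of 4.48 and 4.75 reached the ulcerated median of 4.45. The lower of their chief and parietal scores lay 1.5 above the highest ulcerated score, beyond the uninjured SD of 0.34, which would argue against it. This match rested on Gast, at 71.7 and 125 CPM. Their Pdx1 (5.16 and 6.24 CPM) and Nkx6-3 (26.7 and 22.5 CPM) lay below ulcerated replicates 1 to 3, which had at least 8.13 and 34.4 CPM. The comparison therefore cannot exclude more antral tissue in ulcerated replicates 1 to 3. Uninjured replicates 2 and 3 had antral scores of 1.16 and -0.31, below all ulcerated libraries (3.57 to 4.99). These controls thus differed from every ulcerated library in antral markers. The group means were 4.37 ± 0.65 in ulcerated and 2.52 ± 2.49 in uninjured libraries (SD, n = 4 each), with a two-sided exact permutation p of 0.286. A loss of chief and parietal cells or of their transcripts at the ulcer may account for the pattern and stays open, as does a sampling of other stomach regions that the antral markers do not trace.

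Hepatocyte transcripts were present in the 4 ulcerated libraries and in uninjured replicate 1. Of 16 liver genes outside the fixed lists, picked without acute phase genes after this pattern was seen, at least 14 lay 4-fold or more above the median of the other 3 libraries in each of these 5, which is consistent with liver tissue carried into the samples. Albumin (Alb) reached 15918 CPM in ulcerated replicate 2 and 1915 CPM in uninjured replicate 1. By the labels uninjured replicate 1 came from a healthy control, so a response of the stomach to the ulcer would not account for its hepatocyte transcripts. Its score of 8.45 lay above the 6.50 of ulcerated replicate 3, and 16 of the 16 outside genes were raised in it. In the 4 ulcerated libraries such a response cannot be told apart from carried liver tissue. The hepatocyte scores overlapped between the groups, with a two-sided exact permutation p of 0.0571.

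Pancreatic acinar transcripts were high in ulcerated replicate 1 alone. Of the list members, Ctrb1 had 3514 CPM there against at most 10.03 CPM elsewhere and Amy2b 2045 against 33.1 CPM. Of 12 pancreatic genes outside the fixed lists, picked after this pattern was seen, 10 lay 10-fold or more above the highest other library, and the exceptions were Prss1 and Pnliprp2. Pancreatic tissue carried into that sample may be the source, and no biological explanation was tested, since the pattern lies in 1 sample. Clps, at 677 CPM, was higher in every uninjured library.

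The number of genes called between ulcerated and uninjured tissue was set against the 35 splits of the 8 libraries. Only 1 of them, the real one, gave as many as 1815 genes. If the replicate numbers do not pair the samples, which the labels leave open, this argues against chance but does not exclude it. It is the smallest share that 35 splits can give, and the test was chosen after the results were seen. If the numbers do pair the samples, exchanges within pairs give 8 splits, too few for a share under 0.05. The highest other split, which exchanged ulcerated replicate 3 and uninjured replicate 1, gave 1065 genes and parted the libraries by hepatocyte score. Chance could not be excluded for the number of lists called with the preset correlation, since 3 of the 35 splits, the real one included, gave as many as 20 lists and the highest other split gave 20.

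Single libraries stood apart from the other 3 of their group in 25 of 306 groups of 4 checked, against 15.3 by chance, with a gap divided by the range of the group above the 95% critical value of Dixon's test. Uninjured replicate 2 was lowest of its group in the parietal cell score (0.832), Atp4b (0.836), Slc4a2 (0.878) and Chga (0.86), and highest in the cytokine score (0.954), S100a8 (0.855), Dmbt1 (0.83), Krt19 (0.891), Nos2 (0.93), Thbs1 (0.905) and Plaur (0.835). Ulcerated replicate 3 was highest of its group in the general epithelium score (0.86) and Clu (0.962), and lowest in Adam12 (0.859), H19 (0.869) and Thbs1 (0.958). Ulcerated replicate 1 was highest in the acinar score (0.895) and lowest in the interferon response score (0.861) and Myh11 (0.86), and ulcerated replicate 4 was lowest in the cytokine score (0.901). Uninjured replicate 4 was highest in the acinar score (0.91) and in Hba-a1 and Hba-a2 (0.97 each, from identical and uncertain counts) and lowest in the Hedgehog score (0.896), and uninjured replicate 1 was highest in Ccl7 (0.925).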

How the results depend on the processing

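The alternatives with the hepatocyte score as a covariate, with only the 5 libraries of higher hepatocyte score and without both ulcerated replicates 1 and 2 were chosen after seeing the data. Against 865 genes higher and 950 lower, total counts gave 541 higher, a filter of 10 CPM in 4 libraries 434 and 585, for which fewer genes were tested, and the DESeq2 Wald test 2299 and 1711. Leaving out 1 library gave 0 to 2406 genes higher and 0 to 1911 lower, the covariate 2 and 3, and the fit without ulcerated replicates 1 and 2 gave 0 and 0. The 5 libraries held 4 ulcerated ones and only 1 uninjured one, so only medians are given for them. With the replicate number as a block 1374 genes were higher and 1211 lower. The labels do not say that the numbers pair the samples, and the values left it open, since the deviations of replicates 1 to 4 from their group correlated at 0.67, -0.15, 0.60 and 0.31 between the groups and 3 of the 4 ulcerated libraries correlated best with the uninjured library of their own number. DESeq2 size factors, upper-quartile scaling, no filter, limma-voom and all 10 libraries in 1 fit gave 665 to 879 higher and 728 to 966 lower. With an estimated correlation 0 lists were called higher and 0 lower, against 12 and 8, and the medians of SPEM markers (0.94), parietal (-2.35) and chief cells (-2.76) no longer passed, at adjusted p = 0.313, 0.243 and 0.193. In the other alternatives these 3 lists kept their call, leaving aside the 5 libraries, which had only 1 uninjured library and allow no call. Leaving out 1 library, the medians ranged from 0.83 to 1.09, from -2.84 to -2.06 and from -2.78 to -2.51, and the lists called from 11 to 14 higher and from 8 to 9 lower. Without both ulcerated replicates 1 and 2 the medians of these 3 lists were 1.21, -1.62 and -2.15. The medians of 7 lists changed sign under at least 1 alternative, with ranges over all alternatives of -0.24 to 0.77 for interferon response, -0.25 to 0.31 for general epithelium, -1.98 to 5.42 for squamous epithelium, -0.59 to 0.37 for erythroid, -0.99 to 8.74 for pancreatic acinar, -0.20 to 0.17 for hypoxia and glycolysis and -0.44 to 0.62 for intestinal genes. The interferon and general epithelium medians lay near 0 in the main test, which pointed upward. Interferon response had 0.21 without uninjured replicate 3, where it passed, 0.22 without uninjured replicate 2 and 0.11 without ulcerated replicate 1, where it did not, and -0.24 without uninjured replicate 4. With the covariate it had 0.70 and passed (camera adjusted p = 0.001), and in the 5 libraries it had 0.77. General epithelium passed at 0.31 with the covariate (adjusted p = 0.00939). Squamous epithelium, called higher in the main test (adjusted p = 0.0179), passed at -1.98 with the covariate (5.45e-06) and was at -0.65 in the 5 libraries. Without ulcerated replicates 1 and 2, the first of which held the acinar transcripts, erythroid genes passed at -0.59 and pancreatic acinar genes at -0.36 (adjusted p = 0.00475 and 0.00617), and the lowest acinar median, -0.99, came with the covariate and did not pass. Of the 122 genes taken by the naming rule, 75 passed in the main test, and none of these reversed where it was tested under these settings. All 75 lost their call without ulcerated replicate 1, ulcerated replicate 2 or uninjured replicate 3, and 73 did without uninjured replicate 4. For the other named genes a change of sign was not counted unless the gene passed in 1 of the 2 fits compared. A count minimum of 30 for organoids gave 1781 genes at least 4-fold lower, against 1029, since more genes were counted. Where not stated, the cause was not tested.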

Other observations

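The genes below were chosen after their values were seen, and the tests of shared genes between ulcerated tissue and organoids were planned before.

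Several genes outside the lists passed the edgeR test, and no gene group was tested here. Pigr, the receptor that carries antibodies across epithelium, rose to 668 ± 99.9 from 86.5 ± 56.3 CPM, the tight junction gene Cldn2 to 96.8 ± 16.4 from 13.0 ± 6.96 CPM and the adhesion gene Ceacam1 to 159 ± 37.4 from 26.2 ± 12.1 CPM (SD, n = 4 each). The log2 fold change was 3.52 for Reg3g and 2.13 for the imprinted gene Mest. Among single genes that fell were the creatine kinase Ckb (-1.77), the lactate dehydrogenase Ldhb (-2.13), the ketone body enzyme Oxct1 (-1.97) and the glucose transporter Slc2a4 (-1.80). The protease Furin fell to 240 ± 124 from 1040.4 ± 319 CPM (SD, n = 4 each), and the cholecystokinin receptor Cckar (-2.50) and Trim50 (-2.54) also fell. Besides Sds, the called genes known from liver included Upp2 (4.85) and Gls2 (4.45).

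Genes higher in ulcerated tissue were compared with genes at least 4-fold higher in organoids over 11068 genes. Both held for 147 of the 419 genes higher in ulcerated tissue, against 22.8 by chance, an odds ratio of 12.1 (95% interval 9.6 to 15.1, adjusted p of 9.17e-83 by Fisher's exact test over genes, which are not independent replicates). Examples were Cldn2, Reg3g, Prss22 and Cxcl5. Of 752 genes lower in ulcerated tissue 262 were at least 4-fold lower in organoids, against 69.6 by chance, an odds ratio of 6.7 (adjusted p of 8.42e-92 by the same test). The opposite pairings held 37 genes higher in ulcerated tissue and lower in organoids, against 38.8 by chance, and 3 lower in ulcerated tissue and higher in organoids, against 41 by chance. A shared epithelial response and a loss of the same mature cell transcripts may account for the overlap. Other causes, such as a lower share of chief and parietal cells in both, were not separated. The organoid side rests on 1 library each, and the intact one held less Cldn2 and Reg3g than any uninjured library.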
